A study of Homo sapiens with 26 samples.

How the data were processed

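Gene expression was measured on 26 Affymetrix arrays with 54675 probe sets, 20 of dendritic cells grown from monocytes and 6 of monocytes, in the 7 groups given by the sample labels. The values are signal intensity on a linear scale as deposited, made by the authors with GCOS 1.2, according to the submitters' processing notes. Each array had been scaled to a common 2% trimmed mean, which lay between 249.96 and 249.97 on every array. The values used here came without detection calls, so a filter on level stood in for them. The number of arrays limits the precision. The p-values of single genes rest on a spread between cultures that is pooled over all 7 groups, monocytes included. A gene's SE can therefore differ from the spread within the groups compared.

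The analysis used R 4.3.3, limma 3.58.1 and the data.table package (version 1.17.8), with figures drawn by matplotlib 3.10.9. Values were taken as log2(value + 25.0), the pseudocount being 0.1 of the mean trimmed mean. Probe sets above the median of their own array in at least 3 arrays were kept, 36657 in number. Of all probe sets, 41097 named 1 gene, 1801 several and 11721 none, 62 were controls (some of which name a gene and are counted there too), and 79 of sex-linked genes were left out. For the 7490 genes with over 1 probe set, the one with the highest mean log2 value over all arrays was used, which gave 15440 genes. Probe sets with several genes or none were tested apart. Near-identical genes such as FCGR2A and FCGR2B were read as the annotation names them, and a value given for one of them may mix several.

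One limma model (lmFit and eBayes) with a mean for each of the 7 groups was fitted over all arrays, with 19 residual and 5.04 prior degrees of freedom, and each comparison was a contrast of that model. Genes with a Benjamini-Hochberg adjusted p under 0.05 were said to pass. Differences of effects (dendritic cells against monocytes, antibody against interferon alpha) were contrasts of the same model. The donor was added as a fixed block in an alternative with 11 residual and 4.12 prior degrees of freedom, since arrays of 1 replicate number within a set share a donor. The labels code the donor for 2 of the 3 interferon pairs, and the remaining 2 arrays were taken as the third pair by elimination. A donor code on 1 array conflicted with its title and the title was used. Residuals of 19 pairs of 1 donor correlated at 0.221 to 0.647 (median 0.405) against a median of -0.118 between donors. In a search among arrays of other treatments, 26 of 26 arrays lay closest to an array of their own donor. For the third interferon pair, which gave the 0.647, the search held no other candidate, so that match was fixed in advance. It does not test the pairing of those 2 arrays.

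The 28 gene lists, the comparisons, the model, the filter, the rule for named genes and most alternatives were fixed before the data were examined. Lists covered interferon-stimulated genes, interferons and receptors, maturation, immature cell and uptake receptors, cytokines, chemokines, NF-kB targets, prostaglandin E2 and cAMP response, Fc receptors, MHC class I and II, Toll-like receptors, complement, checkpoint ligands, cholesterol, lysosome, metallothioneins, heat shock, cell cycle, ribosomal proteins, and markers of monocytes, T, NK and B cells, platelets, erythroid cells, neutrophils and plasmacytoid dendritic cells. Each was tested by camera with a preset correlation of 0.01, with an estimated correlation, and by fry, with adjustment over the lists of a comparison. An adjusted p given for a list is camera's with the preset correlation unless stated otherwise. The estimated correlation was higher, such as 0.469 for interferon-stimulated genes and 0.156 for maturation genes. There, p with the preset value overstate the evidence. Several lists share genes, such as IDO1, EBI3, IRF1 and CXCL10. Named genes were, per comparison, the 8 highest and 6 lowest log2 fold changes among genes that passed with the same sign in every donor pair, the called member of each list with the largest rise and the largest fall, a fixed set of receptor, maturation, cytokine and interferon genes, and the 5 largest differences each way of each difference of effects. Of the fixed set, 3 genes are not analysed here. Genes outside the rule are named where a list had 5 or fewer calls in a direction.

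The procedure was tested on simulated data, in which 49.3%, 91.0% and 98.5% of genes changed by 1, 2 and 3 on the log2 scale were found in the antibody comparison of dendritic cells, and 22.4%, 82.1% and 97.0% in that of monocytes. The simulation gave every donor the same change and had independent noise, no donor effect and no deviating array. Among named genes that passed, 18, 26, 19 and 9 in the antibody, cocktail, direct and interferon comparisons had over 1 probe set, another probe set pointed the other way for 0, 1, 2 and 1, and 0 passed in the other direction. Alternatives were quantile normalization, scaling to 1 median, pseudocounts of 75.0 and 8.33, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, all probe sets, leaving out probe sets that can hit several transcripts, eBayes with trend and robust, array weights, the donor as fixed or random block, fitting only the arrays compared, a 2-fold minimum, and leaving out each array. Leaving out whole donors, and camera with donor block and estimated correlation together, were added after the data were seen. Other splits of the arrays were drawn with seed 20241.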

Results

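Transcript levels were measured on 26 arrays of human blood cells from healthy donors after 24 h of culture where the labels give a time, which they do not for replicates 2 and 3 of the interferon set. Dendritic cells grown from monocytes had received an isotype control antibody (n = 5), an antibody against FcgRIIB, the inhibitory Fc receptor for IgG (n = 5), or a maturation cocktail of TNF-alpha, IL-1 beta, IL-6 and prostaglandin E2 (n = 4). A separate set of dendritic cells was kept without interferon alpha (n = 3) or given it at 1000 U/ml (n = 3). CD14-positive monocytes had received the isotype control (n = 3) or the antibody against FcgRIIB (n = 3). Arrays with the same replicate number within a set came from 1 donor, which for interferon replicate 3 was taken by elimination. The genes tested numbered 15440. The number of arrays limits the precision of every value below.

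The first comparison asked how dendritic cells change when FcgRIIB is bound by the antibody, against isotype-treated cells of the same donors (n = 5 and 5 for every gene in this comparison). Genes of mature dendritic cells were among those that rose most. IDO1, which breaks down tryptophan, rose by 5.16 on the log2 scale (SE 0.72, adjusted p = 8.28e-05), and EBI3, a subunit of IL-27 and IL-35, rose by 4.34 (SE 0.56, adjusted p = 3.16e-05). CCL5, a chemokine that draws T cells, rose by 4.86 (SE 0.58, adjusted p = 1.48e-05), IL2RA, the alpha chain of the IL-2 receptor, by 4.44 (SE 0.52, adjusted p = 1.41e-05), and CRLF2, the receptor for thymic stromal lymphopoietin, by 4.17 (SE 0.40, adjusted p = 7.77e-07). MUCL1 (4.64, SE 1.01), the collagenase MMP1 (4.30, SE 1.23) and the hyaluronan-binding protein TNFAIP6 (4.04, SE 0.65) completed the 8 highest, with adjusted p of 0.00686, 0.0368 and 4.08e-04. The 6 lowest were CD1A and CD1C, which present lipids (-3.74, SE 0.48, and -3.08, SE 0.64), the G protein regulator RGS18 (-3.31, SE 0.66), the coagulation factor subunit F13A1 (-3.26, SE 0.63), the adenosine receptor ADORA3 (-3.08, SE 0.38) and the IL-1 decoy receptor IL1R2 (-3.01, SE 0.52). Their adjusted p lay at or below 0.00470, and all 14 genes had the same sign in 5 of 5 donors.

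Of 29 maturation genes, 20 rose, 0 fell and 9 did not pass (23 rose adjusted over the list alone), with a median of 2.18 and an adjusted p of 9.37e-35 (1.84e-04 with an estimated correlation). Among them CCR7, which guides cells to lymph nodes, rose by 2.92 (SE 0.53), the T cell co-stimulator CD80 by 2.42 (SE 0.55) and the maturation marker CD83 by 1.19 (SE 0.33). CD40 stood at 1.09 (SE 0.34, adjusted p = 0.0577) and passed with the donor as a block (adjusted p = 0.00286) and with a larger pseudocount (0.0444), and CD86 stood at 0.59 (adjusted p = 0.471). Of 23 targets of NF-kB, a transcription factor of inflammation, 18 rose, 0 fell and 5 did not pass (19 adjusted over the list alone; median 1.60, adjusted p = 1.85e-27), including IRF1, an activator of interferon-response genes (2.46, SE 0.23). Of 24 receptors of immature cells and of uptake, 8 fell, 0 rose and 16 did not pass (10 fell adjusted over the list alone, 15 fell with the donor block), at a median of -1.43 and an adjusted p of 1.68e-07. That call ended with an estimated correlation (adjusted p = 0.0570 with an estimated correlation), and CD209, a lectin that takes up glycans, stood at -0.77 (adjusted p = 0.398).

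Of 58 interferon-stimulated genes, 31 rose, 0 fell and 27 did not pass (42 rose adjusted over the list alone), with a median of 1.43 and an adjusted p of 1.71e-31 (0.0326 with an estimated correlation, and 0.00167 by fry). IFI44L, which had the largest rise of the list, stood 3.78 higher (SE 0.85, adjusted p = 0.00859, higher in 4 of 5 donors), and the antiviral GTPase MX1 rose by 2.73 (SE 0.68, adjusted p = 0.0174). IFIT1, which binds viral RNA, stood at 1.70 (adjusted p = 0.226) and the chemokine CXCL10 at 0.72 (adjusted p = 0.538). The mean level of the list was 8.46 in antibody replicate 3, against 9.62 to 10.34 in the other 4 antibody arrays and 8.25 to 8.40 in the isotype arrays. Leaving out antibody replicate 4 or antibody replicate 5 left 20 of the 58 rising. With the donor block and an estimated correlation together the adjusted p of this list was 0.132. None of the 16 interferon genes and interferon receptors tested passed by limma (median -0.13), and 1 higher and 1 lower did with the donor block. The list named 26, and IFNB1 and several interferon alpha genes were not tested. The result therefore does not tell whether those interferon genes changed.

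**Figure D1:**
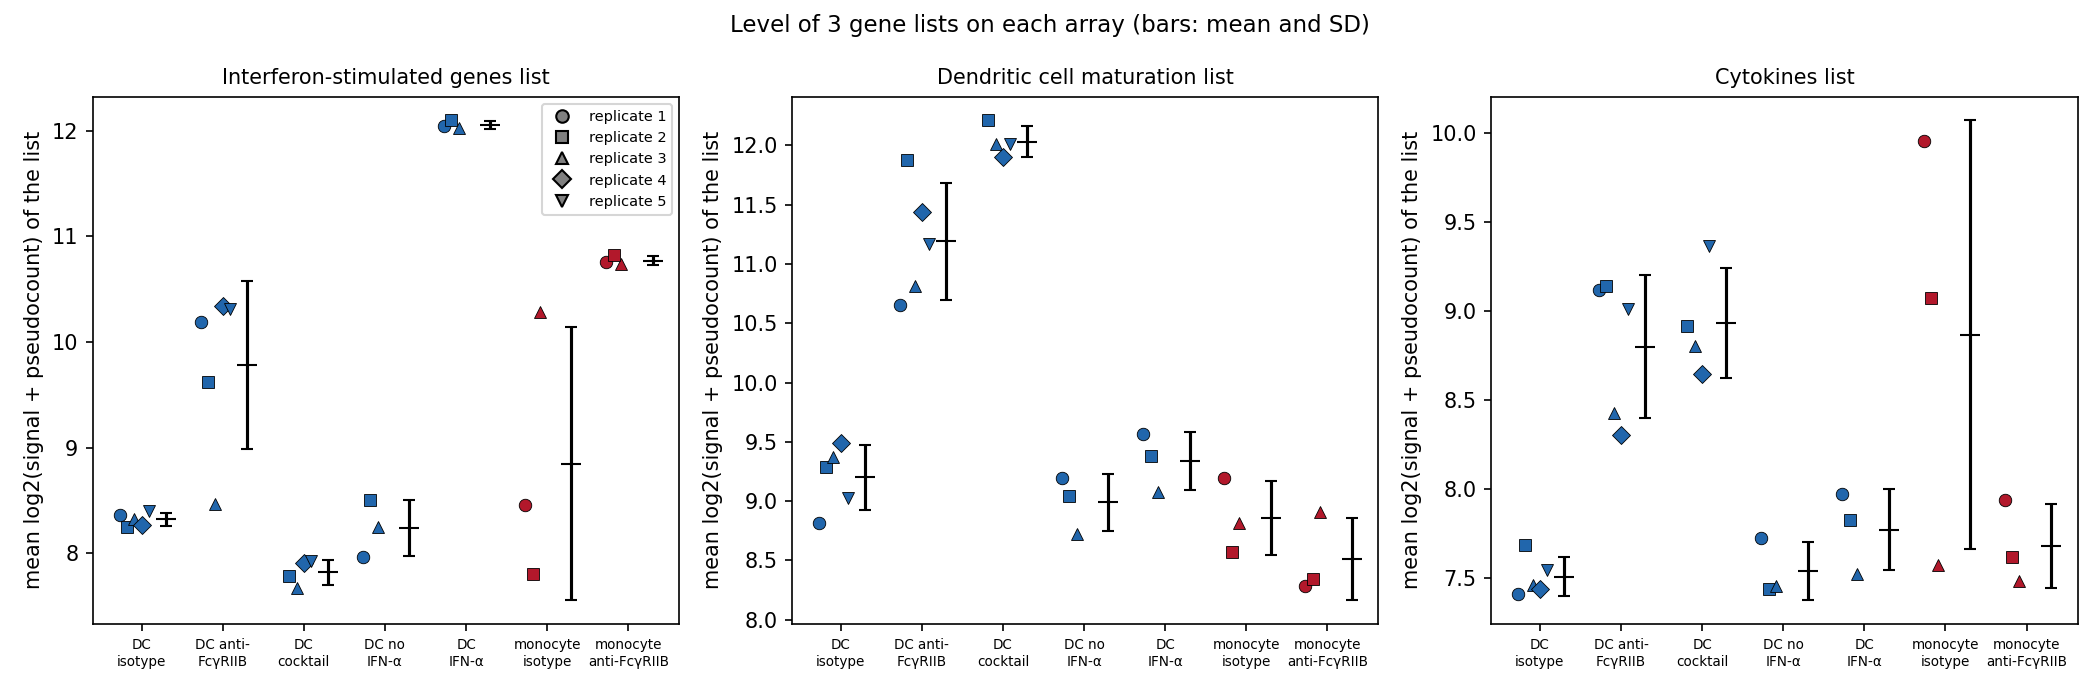
Mean log2 signal of the genes of 3 fixed lists on each array, by group and replicate, with bars for the group mean and SD. The interferon-stimulated genes lay between 8.25 and 8.40 on the DC isotype arrays and between 12.03 and 12.10 on the IFN-alpha arrays.

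Cytokine genes rose in 8 of 22 cases with 0 falling and 14 not passing (10 rose adjusted over the list alone; median 1.07, adjusted p = 8.60e-09), among them IL6 by 3.75 (SE 1.09, adjusted p = 0.0402) and IL12B, a subunit of IL-12 and IL-23, by 2.10 (SE 0.43, adjusted p = 0.00392). TNF stood at 0.69 (adjusted p = 0.460) and IL10 at 0.27, neither passing. Without antibody replicate 5, isotype replicate 1 or isotype replicate 2, 5 cytokine genes rose, and with the donor block and an estimated correlation the adjusted p of the list was 0.0614. Of 26 chemokines, 7 rose, 0 fell and 19 did not pass (11 adjusted over the list alone, 13 with the donor block; median 0.86, adjusted p = 4.69e-10). Genes of the prostaglandin E2 and cAMP response rose in 6 of 21 cases and fell in 1, with 14 not passing (9 and 1 adjusted over the list alone; median 0.93, adjusted p = 3.04e-08). PDE4B, which breaks down cAMP, rose by 3.39 (SE 0.32) and IL1R2 was the 1 that fell. Genes of cholesterol synthesis and uptake rose in 9 of 16 cases, 0 fell and 7 did not pass (12 adjusted over the list alone; median 1.03, adjusted p = 4.12e-12), including HMGCS1, an enzyme of sterol synthesis (1.93, SE 0.33).

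Genes that load peptides on MHC class I rose in 6 of 20 cases, 0 fell and 14 did not pass (9 adjusted over the list alone, 9 higher and 1 lower with the donor block; median 0.54, adjusted p = 5.76e-08), led by the peptide transporter TAP1 (1.82, SE 0.26). Checkpoint and apoptosis ligands rose in 4 of 18 cases and fell in 1, with 13 not passing (5 and 1 adjusted over the list alone; median 0.46, adjusted p = 0.00152). The 4 were IDO1, the cytokine signal inhibitor SOCS3 (2.73, SE 0.61), the PD-1 ligand PDCD1LG2 (1.49, SE 0.41) and the amino acid oxidase IL4I1 (1.16, SE 0.34), which missed the threshold after quantile normalization (adjusted p = 0.0722). CD200R1, an inhibitory receptor, fell by 1.49 (SE 0.30). The adjusted p of each of these lists was 0.132 with the donor block and an estimated correlation.

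Among 22 Fc receptor and signalling genes, 3 fell, 0 rose and 19 did not pass (8 fell adjusted over the list alone, 9 with the donor block; median -0.48, adjusted p = 0.00300, and adjusted p = 0.240 with an estimated correlation). These were the phosphatase INPP5D, which acts downstream of FcgRIIB (-1.28, SE 0.35), the neonatal Fc receptor FCGRT (-1.10, SE 0.32) and the ubiquitin ligase CBL (-0.76, SE 0.19). Another probe set of INPP5D stood at -0.42. FCGR2B itself, the gene of FcgRIIB, read by a probe set that near-identical genes may share, stood at -0.34 (SE 0.85, adjusted p = 0.910) and FCGR2A, its activating counterpart, at 0.25 (adjusted p = 0.899). Complement genes rose in 3 of 17 cases, 0 fell and 14 did not pass (5 adjusted over the list alone, 7 with the donor block; median 0.39, adjusted p = 0.00607, and adjusted p = 0.240 with an estimated correlation), namely CFB (3.77, SE 0.58), C1S (3.09, SE 0.44) and CFP (2.06, SE 0.45). Among 25 Toll-like receptor genes IRF1 rose and TLR4, the receptor for lipopolysaccharide, fell by 1.91 (SE 0.32), 23 did not pass, and the list as a whole did not pass (adjusted p = 0.658; 2 rose and 1 fell adjusted over the list alone, 4 and 5 with the donor block). Genes of MHC class II (adjusted p = 0.229), lysosome (0.0707, and 0.0247 after quantile normalization), metallothionein and oxidative stress (0.208), heat shock (0.841), cell cycle (0.841) and ribosomal protein (0.6249) lists did not pass as lists. Their members that passed were CD9 (-1.45, SE 0.42) and HEXA (-1.06, SE 0.24), which fell, and SLC7A11, which rose by 1.22, with GCLC at -1.56. The probe set nearest 0 stood at -0.09 for CD9, -0.12 for HEXA and -0.26 for GCLC. The donor block gave 5 MHC class II and 3 lysosome genes as lower. It gave 2 heat shock genes as higher and 1 as lower. The genes named outside the rule, here FCGRT, CBL, C1S, CFP, SOCS3, PDCD1LG2, IL4I1 and SERPINA1, were chosen after their values were seen.

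Markers of other cells were measured as lists too. Monocyte markers rose as a list (median 0.94, adjusted p = 0.0221, and adjusted p = 0.503 with an estimated correlation), with S100A9 (2.82, SE 0.75) and SERPINA1 (2.52, SE 0.55) passing and 12 of 14 not passing (3 adjusted over the list alone, 6 higher and 2 lower with the donor block, where the list had 0.0526). Their mean level was 10.04 in antibody replicate 5 and higher still in antibody replicate 1, against 8.22 to 8.55 in the other antibody arrays and 8.11 to 9.26 in the isotype arrays, and CD14 stood at 1.05 (adjusted p = 0.527, and 0.0281 with the donor block). FCRLA of the B cell list rose by 1.36, and in the neutrophil list the collagenase MMP8 rose by 1.83 and the chemokine receptor CXCR2 fell by 2.28. The T cell (adjusted p = 0.652), NK cell (0.6249), B cell (0.708), platelet (0.658), erythroid (0.841), neutrophil (0.544) and plasmacytoid dendritic cell (0.258) lists did not pass. The donor block gave 1 T cell, 1 NK cell, 2 platelet and 1 plasmacytoid marker as higher. Median, mean and test differed in sign for the interferon and receptor, heat shock, B cell and platelet lists.

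In all, 938 genes passed by limma, 519 higher and 419 lower, and 677 of them differed at least 2-fold. All 938 were among the 2731 that passed with the donor as a block (1149 higher and 1582 lower). The share that was higher was 55.3%, and 66.1% when arrays were scaled to 1 median (410 higher and 210 lower). Without antibody replicate 2 the count was 453 and without antibody replicate 4 it was 598. On isotype replicate 3 the 3' to 5' control ratio on the log2 scale was 1.83 for GAPDH and 2.25 for ACTB, against -0.04 to 0.03 and 0.01 to 0.09 on the other 4 isotype arrays, and 710 genes passed without it. Over the 5 comparisons between treatments, 20 two-sided exact permutation tests of control ratios had a lowest adjusted p of 0.212, where a single differing ratio could not have passed, since the smallest possible p was 0.00794 to 0.1.

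**Figure D2:**
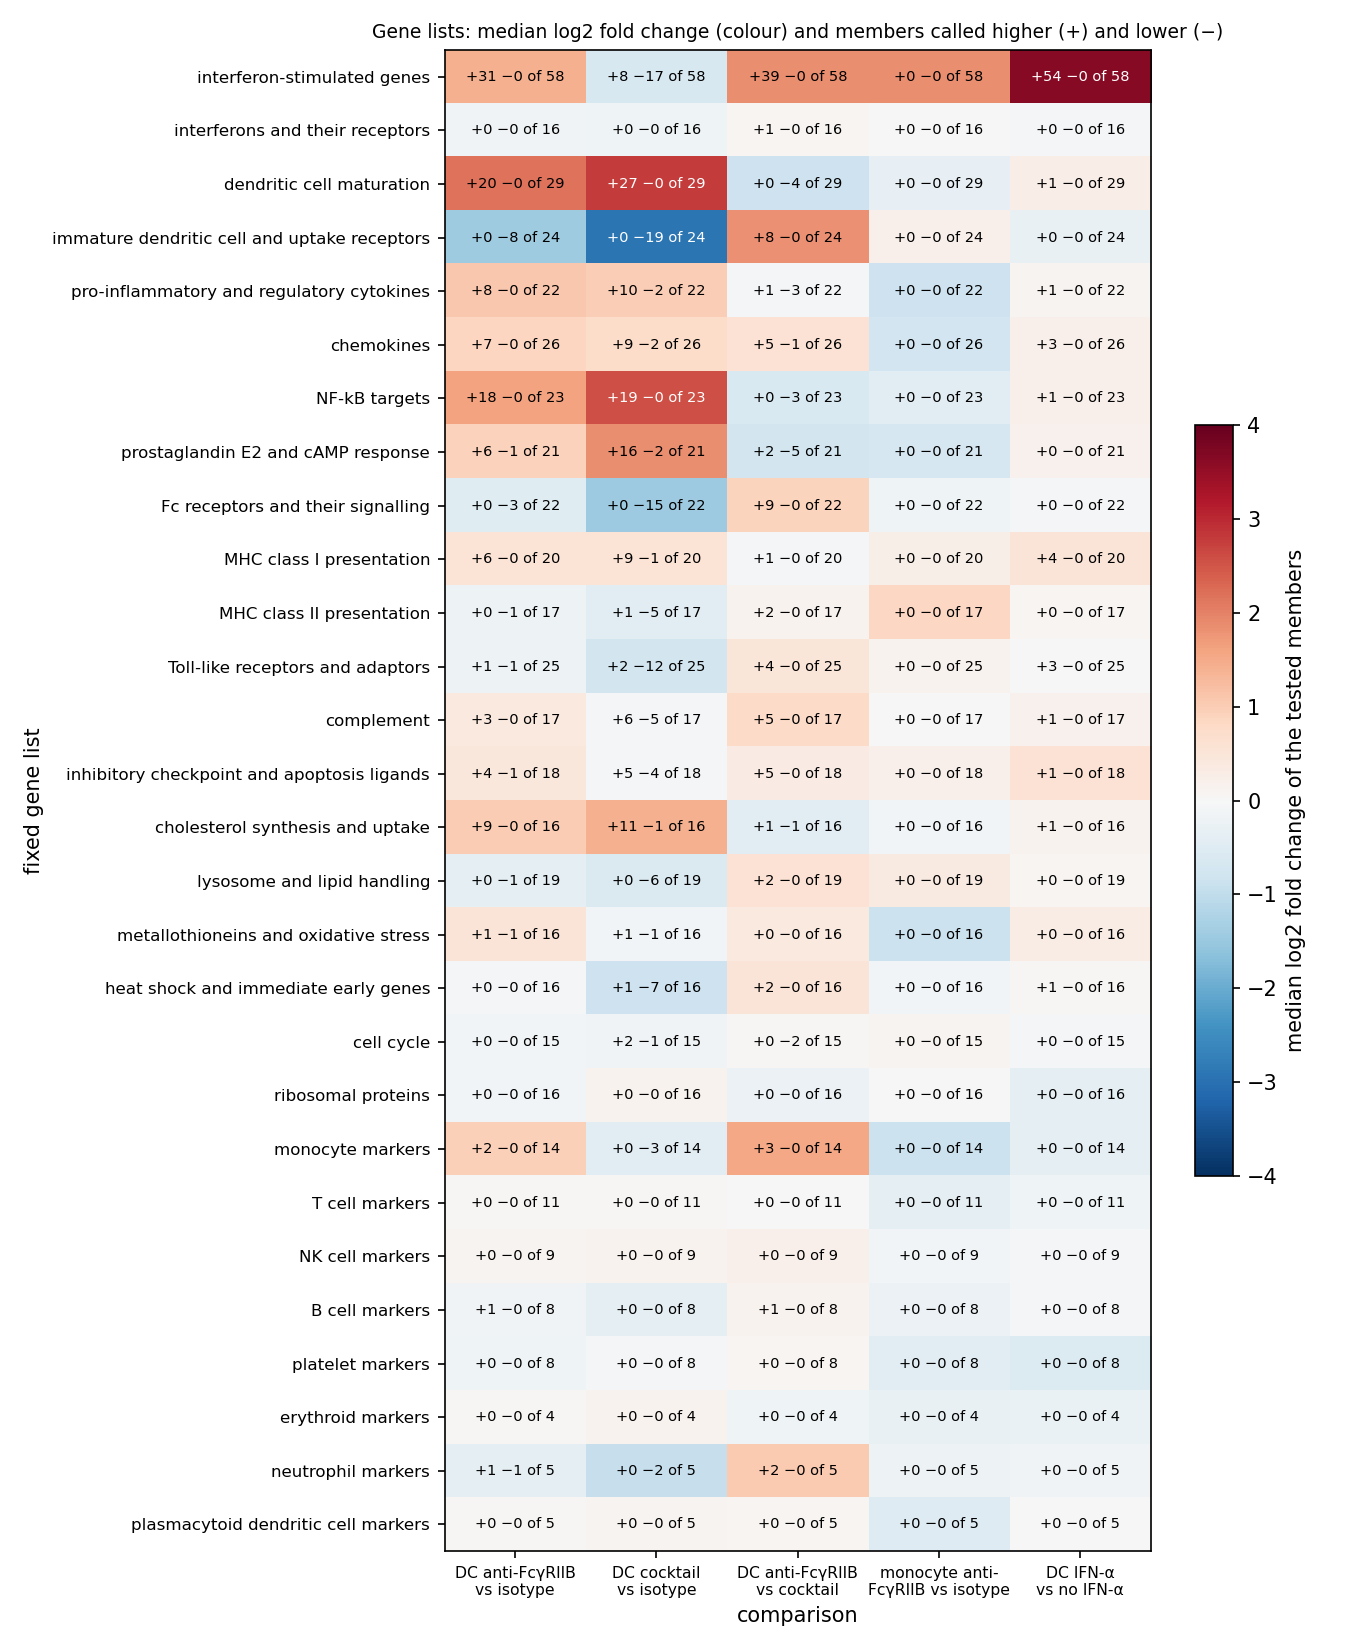
Median log2 fold change of each fixed list in the 5 comparisons (colour), with the number of members that passed higher (+) and lower (−) of those tested. Maturation genes had medians of 2.18 with the antibody and 2.81 with the cocktail, and interferon-stimulated genes 1.43 and -0.65.

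The cocktail comparison showed what a standard maturation stimulus does in the same system (n = 4 and 5 for every gene in this comparison). IDO1 rose by 6.90 (SE 0.76, adjusted p = 4.42e-07), IL12B by 5.95 (SE 0.45, adjusted p = 4.18e-09), CRLF2 by 5.95 (SE 0.43, adjusted p = 1.84e-09) and EBI3 by 5.76 (SE 0.59, adjusted p = 2.10e-07). The matrix protein THBS1 (5.50, SE 0.50), the glutamate transporter SLC1A2 (5.43, SE 0.49), the chemokine CCL20 (5.25, SE 1.22) and the kinase phosphatase DUSP4 (5.21, SE 0.67) followed. The 7 probe sets of THBS1 ranged from 0.02 to 6.63. The 6 lowest were F13A1 (-5.89, SE 0.67), CD1A (-5.65, SE 0.51), CD1C (-5.53, SE 0.68), the condensin subunit NCAPH (-5.21, SE 0.41), IL1R2 (-5.14, SE 0.55) and the surface receptor SLAMF8 (-5.09, SE 0.46). All 14 had the same sign in 4 of 4 donors with both arrays.

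Maturation genes rose in 27 of 29 cases with 0 falling and 2 not passing (28 adjusted over the list alone; median 2.81, adjusted p = 1.06e-26), including CCR7 (3.87), CD80 (3.49), CD40 (2.07) and CD83 (1.80). CD86 stood at 1.02 (adjusted p = 0.0664, and 0.0137 with the donor block). Receptors of immature cells and of uptake fell in 19 of 24 cases, 0 rose and 5 did not pass (21 adjusted over the list alone; median -2.93, adjusted p = 1.79e-11, and 0.0935 with the donor block and an estimated correlation). The high-affinity IgE receptor chain FCER1A fell by 4.65 (SE 1.12, with its other probe set at -0.19) and CD209 by 2.97. NF-kB targets rose in 19 of 23 cases, 0 fell and 4 did not pass (20 adjusted over the list alone; median 2.59, adjusted p = 2.88e-19), with TNFAIP6 at 4.38 and IRF1 at 3.16. Prostaglandin E2 and cAMP genes rose in 16 of 21 cases, 3 did not pass (17 adjusted over the list alone; median 1.86, adjusted p = 1.29e-08), and IL1R2 and the prostaglandin receptor PTGER2 (-1.34, SE 0.33) fell. Cholesterol genes rose in 11 of 16 cases, 4 did not pass (12 adjusted over the list alone; median 1.43, adjusted p = 2.77e-08), led by HMGCS1 (3.44), while CH25H, which makes an oxysterol, fell by 4.07.

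Interferon-stimulated genes went both ways, with 8 higher, 17 lower and 33 not passing (9 and 21 adjusted over the list alone; median -0.65, adjusted p = 0.305). The exonuclease ISG20 rose by 4.73, the antiviral membrane protein IFITM3 fell by 4.22 (SE 0.81), and MX1 stood at -1.53 (adjusted p = 0.134). IFIT1 was lower by log2 -2.20 (SE 0.80, adjusted p = 0.0458), a call that ended after quantile normalization (adjusted p = 0.0525) and with a larger pseudocount (0.168). IFIT3 and XAF1, singled out after their values were seen, were the 2 genes higher with the antibody (2.26, SE 0.58, and 1.45, SE 0.41) and lower with the cocktail (-2.35, SE 0.62, and -2.44, SE 0.43). With the antibody IFIT3 was higher in 4 of 5 donors and XAF1 in 5 of 5.

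Fc receptor genes fell in 15 of 22 cases, 0 rose and 7 did not pass (16 adjusted over the list alone; median -1.46, adjusted p = 5.24e-07, and adjusted p = 0.0529 with an estimated correlation). FCGR2B fell by 3.61 (SE 0.91, adjusted p = 0.00405) and FCGR2A by 2.09 (SE 0.63, adjusted p = 0.0148), where its other probe set stood at 0.19. Cytokine genes rose in 10 of 22 cases and fell in 2, with 10 not passing (10 and 2 adjusted over the list alone; median 0.98, adjusted p = 1.39e-04, and adjusted p = 0.104 with an estimated correlation). IL6 rose by 4.13 (SE 1.15), TGFB1, an immunosuppressive cytokine, fell by 3.57, and so did TNFSF13, by 1.63, which missed the threshold after quantile normalization (adjusted p = 0.0510). The other probe set of TGFB1 stood at -1.15. Chemokines rose in 9 of 26 cases with 15 not passing (11 adjusted over the list alone; median 0.73, adjusted p = 0.0109, and adjusted p = 0.284 with an estimated correlation), and CCL2 (-3.55) and CCL8 (-2.68) fell, both of which draw monocytes. MHC class I genes rose in 9 of 20 cases with 10 not passing (10 adjusted over the list alone; median 0.56, adjusted p = 7.91e-04, and adjusted p = 0.0901 with an estimated correlation), with TAP1 at 1.70, and the chaperone CALR fell by 1.16.

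Toll-like receptor genes fell in 12 of 25 cases, with 11 not passing (13 adjusted over the list alone; median -0.73, adjusted p = 0.00601, and adjusted p = 0.165 with an estimated correlation). TLR1 fell by 3.19, and IRF1 and the adaptor TRAF6 (0.69, SE 0.17) rose. Lysosome genes fell in 6 of 19 cases, 0 rose and 13 did not pass (8 adjusted over the list alone; median -0.59, adjusted p = 0.0129, and adjusted p = 0.365 with an estimated correlation), with the lipase LPL at -4.01. The MHC class II list did not pass (adjusted p = 0.223, and 0.0355 after quantile normalization), with HLA-DOB higher (2.00) and 5 lower, namely MARCHF1 (-4.31), HLA-DMB (-3.33), CD9 (-1.76), HLA-DMA (-1.74) and CD81 (-1.24). The other probe set of HLA-DOB stood at 0.10. Complement genes went both ways (adjusted p = 0.751), 6 higher, 5 lower and 6 not passing, with CFB at 3.28 and the falling ones C1QC (-4.48), C1QA (-4.16), C1QB (-3.56), C3AR1 (-2.75) and CR1 (-2.01). Among 18 checkpoint ligands (adjusted p = 0.751) the 5 higher were IDO1, SOCS3 (2.48), PDCD1LG2 (1.96), CD274 (1.51) and IL4I1 (1.22), and the 4 lower were CD200R1 (-3.11), HAVCR2 (-2.14), LGALS9 (-1.41) and LILRB1 (-1.22). In the heat shock and immediate early list (adjusted p = 0.140) 7 of 16 fell, with FOS at -3.11, and ATF3 rose by 1.24.

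The metallothionein and oxidative stress list did not pass (adjusted p = 0.776), with SLC7A11 at 1.495 and GCLC at -1.65, nor did the cell cycle list (0.751), where AURKA (1.40) and MCM2 (0.97) rose and CCNA2 fell by 0.70. The probe set nearest 0 stood at -0.31 for GCLC and -0.20 for CCNA2. No ribosomal protein (adjusted p = 0.246) or interferon and receptor gene (0.877) passed by limma. Under the donor block 1 ribosomal protein gene was lower and 1 interferon or receptor gene higher. Monocyte markers (adjusted p = 0.437) included 3 that fell, CCR2 (-3.06), MNDA (-2.78) and CLEC12A (-2.50), and the call of CCR2 ended with a larger pseudocount (adjusted p = 0.0644). In the neutrophil list (adjusted p = 0.0875) CXCR2 (-4.38) and MPO (-0.91) fell. The T cell (0.720), NK cell (0.751), B cell (0.751), platelet (0.905), erythroid (0.602) and plasmacytoid dendritic cell (0.630) lists did not pass. Fitted with the donor block, 2 metallothionein genes were higher and 3 lower, and 1 monocyte marker was higher and 5 lower. The same fit had 1 T cell, 1 B cell and 1 plasmacytoid marker higher, and 1 NK cell marker lower. Median, mean and test differed in sign for the complement, checkpoint, metallothionein, cell cycle and platelet lists. Names outside the rule in the lists with 5 or fewer calls were chosen after their values were seen.

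Altogether 3902 genes passed by limma, 1527 higher and 2375 lower, and 2540 of them differed at least 2-fold. With the donor as a block the count was 5764, within 1.5 times. Leaving out isotype replicate 3, the array with the high 3' to 5' control ratios, left 3591.

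Antibody and cocktail effects resembled each other across genes, with Pearson r = 0.775 and Spearman rho = 0.739. Both contrasts use the same isotype arrays, and simulated groups with no change gave 0.472, while contrasts built on separate isotype arrays gave 0.555 to 0.699 over 20 splits (median 0.636). With no donor in both contrasts the correlation was 0.511 to 0.704 over 10 splits. The covariance was 0.4001 against 0.0514 in the simulation, and 77.7% of genes had the same sign against 65.6%. Among genes that passed, 439 were higher and 384 lower with both stimuli, counts that have no no-change value here because the isotype arrays are shared. Genes are not independent replicates, so no p was computed across them.

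**Figure D3:**
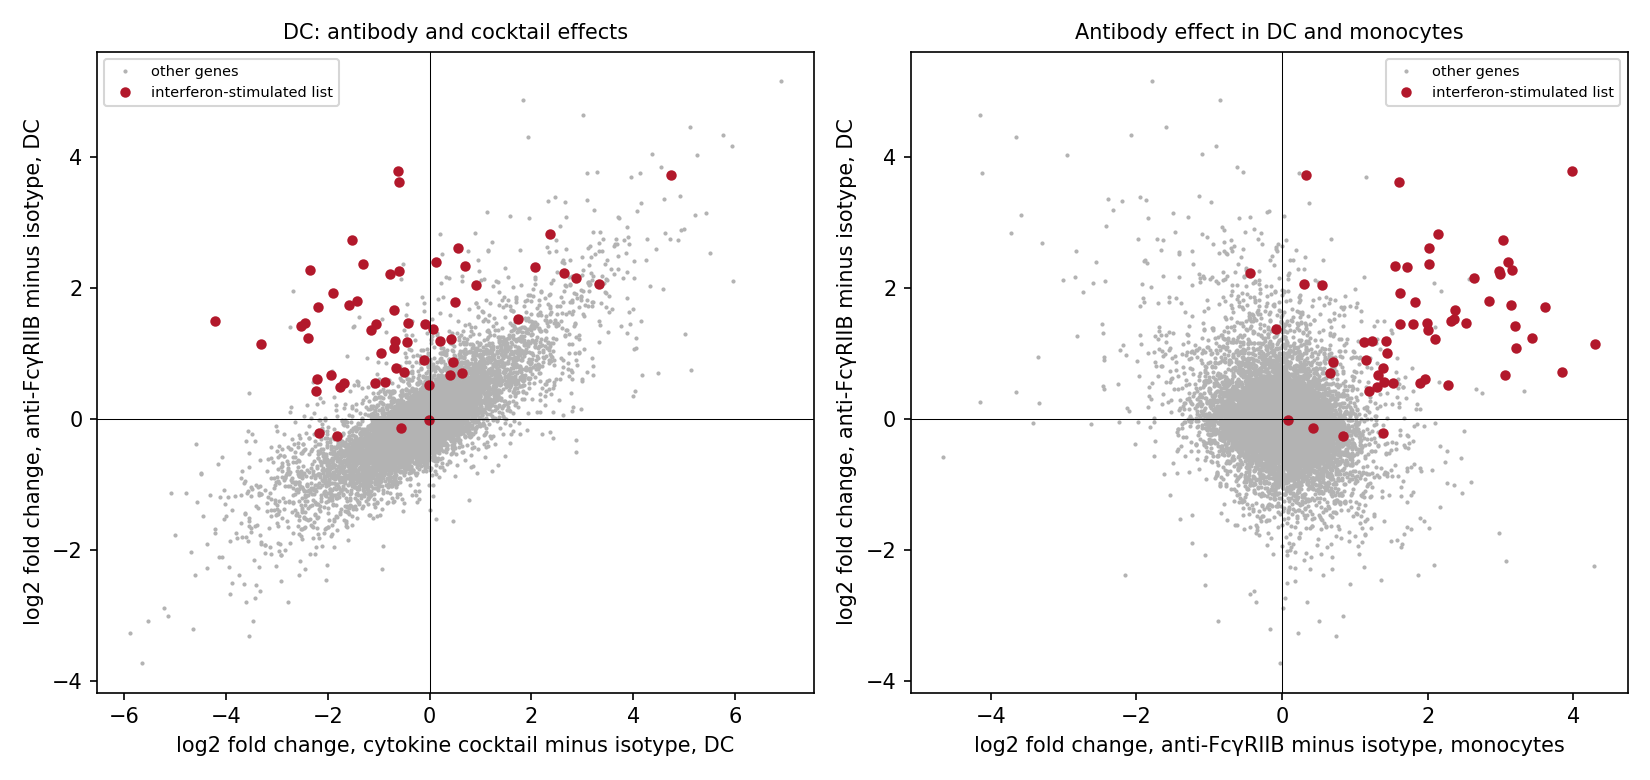
Log2 fold change of each gene with the antibody in dendritic cells (vertical) against that with the cocktail (left) and that with the antibody in monocytes (right), with the interferon-stimulated list in red. The Pearson r across genes was 0.775 on the left and -0.222 on the right.

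The direct comparison asked where the antibody and the cocktail differ (n = 5 and 4 for every gene in this comparison). The genes with the highest levels under the antibody relative to the cocktail were mostly interferon-stimulated. IFITM3 was higher by 5.70 (SE 0.81, adjusted p = 1.01e-04), IFIT3 by 4.61 (SE 0.62, adjusted p = 6.10e-05), LY6E by 4.45 (SE 0.73), IFI44L by 4.40 (SE 0.91), MX1 by 4.26 (SE 0.73) and IFI27 by 4.20 (SE 0.65). The monocyte-attracting chemokine CCL8 (4.62, SE 0.74) and the hexokinase HK3 (4.20, SE 0.56) completed the 8. Lower with the antibody were the neurofilament NEFH (-4.39, SE 0.48), IL12B (-3.85, SE 0.45), the chemokine XCL1 (-3.78, SE 0.47), the desmosome protein DSG2 (-3.72, SE 0.49), the citrullinating enzyme PADI2 (-3.64, SE 0.57) and ALPK2 (-3.61, SE 0.34). All 14 had the same sign in 4 of 4 shared donors.

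Interferon-stimulated genes were higher with the antibody in 39 of 58 cases, lower in 0, and 19 did not pass (44 and 1 adjusted over the list alone; median 1.87, adjusted p = 1.48e-29). Receptors of immature cells and of uptake were higher in 8 of 24 cases, with 16 not passing (16 adjusted over the list alone, 15 with the donor block; median 1.83, adjusted p = 1.02e-09), led by the chemokine receptor CCR1 (3.66, SE 0.34), and CD209 stood 2.20 higher. Fc receptor genes were higher in 9 of 22 cases, with 13 not passing (12 and 1 adjusted over the list alone; median 0.90, adjusted p = 3.73e-07), among them FCGR2B (3.27, SE 0.91, adjusted p = 0.0267) and FCGR2A (2.35, adjusted p = 0.0212, with its other probe set at -0.26). Each of these 3 lists had adjusted p = 0.0692 with an estimated correlation. Maturation genes were lower as a list (median -0.84, adjusted p = 2.93e-09, and adjusted p = 0.0692 with an estimated correlation). The 4 that passed were the co-stimulators TNFSF4 (-2.37) and CD70 (-2.15), the cytokine IL15 (-1.40) and the adhesion molecule CD58 (-1.08), and 25 did not pass (8 adjusted over the list alone, 8 with the donor block). CD83 (-0.61), CD80 (-1.07), CD86 (-0.43) and CCR7 (-0.94) did not pass, and CD40 (-0.98, adjusted p = 0.111) passed with the donor block (0.0103).

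NF-kB targets were lower as a list (median -0.62, adjusted p = 2.73e-06, and adjusted p = 0.163 with an estimated correlation), with BCL2L1 (-1.503), REL (-1.20) and NFKB1 (-1.06) passing and 20 not (7 adjusted over the list alone, 7 with the donor block). NFKB1 missed the threshold after quantile normalization (adjusted p = 0.0797). Prostaglandin E2 and cAMP genes were lower as a list (median -0.74, adjusted p = 9.02e-05, and adjusted p = 0.0744 with an estimated correlation). Lower were THBS1 (-2.98, with 1 of its 7 probe sets at 0.05), SIK1 (-2.56), PDE4D (-2.54), CREM (-1.88) and PDE4B (-1.52), higher were IL1R2 (2.13) and PTGER2 (1.80), and 14 did not pass (2 higher and 8 lower adjusted over the list alone, 8 lower with the donor block). Toll-like receptor genes were higher as a list (median 0.48, adjusted p = 1.05e-04, and adjusted p = 0.0692 with an estimated correlation), with TLR1 (2.39), IRF8 (1.72), LY96 (1.62) and NOD2 (1.49) passing and 21 not (10 and 1 adjusted over the list alone, 9 with the donor block).

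Complement genes were higher as a list (median 0.76, adjusted p = 0.0363, and adjusted p = 0.434 with an estimated correlation), a call that also ended with the donor block (adjusted p = 0.129). C1QC (3.65), C1QA (3.46), C1QB (3.03), SERPING1 (2.68) and C1S (1.52, adjusted p = 0.0708 after quantile normalization) passed and 12 did not (6 adjusted over the list alone). Checkpoint ligands were higher (median 0.34, adjusted p = 0.0237, and adjusted p = 0.163 with an estimated correlation), the 5 being the death ligand TNFSF10 (2.62, adjusted p = 0.0384, and 0.0919 with a larger pseudocount), LGALS9 (1.96), LILRB1 (1.70), HAVCR2 (1.67) and CD200R1 (1.62), with 13 not passing (6 adjusted over the list alone). Cholesterol genes were lower (median -0.43, adjusted p = 0.0104, and adjusted p = 0.193 with an estimated correlation), with HMGCS1 at -1.51, CH25H at 3.48 and 14 not passing (1 higher and 2 lower adjusted over the list alone, 5 lower with the donor block). Lysosome genes were higher (median 0.57, adjusted p = 0.0284, and adjusted p = 0.434 with an estimated correlation), with LPL (2.53) and GPNMB (1.97) passing and 17 not (5 adjusted over the list alone, 6 with the donor block). Heat shock and immediate early genes were higher (median 0.51, adjusted p = 0.01001, and adjusted p = 0.434 with an estimated correlation), with FOS at 2.51, HSPB1 at 1.33 (adjusted p = 0.0597 after quantile normalization) and 14 not passing (5 adjusted over the list alone, 5 with the donor block). Ribosomal protein genes were lower as a list with 0 of 16 passing by limma (median -0.23, adjusted p = 0.01001, and adjusted p = 0.633 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.667).

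Cytokine genes did not pass as a list (adjusted p = 0.375), with TGFB1 higher (2.47, with its other probe set at 0.33) and IL12B, IL23A (-2.97) and IL15 lower. IL6 stood at -0.39 and TNF at 0.76. Chemokines did not pass either (adjusted p = 0.226), although CCL8, CCL2 (3.94), CCL5 (3.03), CCL4 (2.91) and CXCL9 (1.77) were higher and XCL1 lower, and CXCL10 stood at 1.23. The MHC class I (adjusted p = 0.841, PSMB8 at 1.15), MHC class II (0.434, MARCHF1 at 3.15 and CD81 at 1.02), interferon and receptor (0.798, IFNG at 1.08), metallothionein (0.478) and cell cycle (0.439, AURKA at -1.12 and MCM2 at -0.95) lists did not pass. Monocyte markers were higher as a list (median 1.56, adjusted p = 1.43e-04, and adjusted p = 0.189 with an estimated correlation), with S100A9 (2.62), SERPINA1 (2.28) and MNDA (2.02) passing and 11 not (5 adjusted over the list alone, 7 with the donor block). S100A9 and MNDA missed the threshold after quantile normalization (adjusted p = 0.0585 and 0.0546), and CD14 (1.78, adjusted p = 0.205) passed with the donor block (0.00845). Neutrophil markers were higher (median 1.05, adjusted p = 0.01001, and adjusted p = 0.163 with an estimated correlation) with CXCR2 (2.10) and MMP8 (1.68) passing, and FCRLA of the B cell list (0.443) by 1.86. The T cell (adjusted p = 0.826), NK cell (0.958), platelet (0.798), erythroid (0.434) and plasmacytoid dendritic cell (0.893) lists did not pass. By the block fit 4 cytokine genes were higher and 3 lower, and 7 chemokines were higher and 3 lower. The same fit had 13 Fc receptor genes higher and 1 lower, 6 complement genes higher and 2 lower, 2 MHC class I genes higher and 1 lower, and 4 MHC class II genes and 1 metallothionein gene higher. Median, mean and test differed in sign for the MHC class I and cell cycle lists, and names outside the rule in lists with 5 or fewer calls were chosen after their values were seen.

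By limma 1091 genes passed in the direct comparison, 707 higher and 384 lower with the antibody, and 2692 passed with the donor as a block (1725 higher and 967 lower). Without cocktail replicate 4 the count was 672. Of the 707 higher genes, 640 were lower with the cocktail than with isotype, and 35 were higher with the antibody than with isotype. Of the 384 lower genes, 359 were higher with the cocktail than with isotype, and 1 was lower with the antibody than with isotype. The comparisons share arrays, so part of these overlaps is built in.

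The interferon comparison gave a reference for the response of dendritic cells to interferon alpha (n = 3 and 3 for every gene in this comparison). IFI44L rose by 6.97 (SE 1.10, adjusted p = 4.56e-04), IFI27 by 6.80 (SE 0.79, adjusted p = 7.51e-06), RSAD2, which blocks viral budding, by 6.40 (SE 0.81) and MX1 by 6.38 (SE 0.88). IFIT1 (6.36, SE 0.98), IFITM1 (5.86, SE 0.72), CXCL10 (5.85, SE 0.67) and CMPK2 (5.62, SE 0.83) completed the 8 highest. The 6 lowest were TOP1MT (-2.58, adjusted p = 0.00687), ZNF704 (-2.10, adjusted p = 0.0252), ENC1 (-2.01, adjusted p = 0.0441), SGMS2 (-2.00, adjusted p = 4.76e-04), ENHO (-1.86, adjusted p = 0.0154) and ACO1 (-1.79, adjusted p = 0.0129, with its other probe set at 0.02). The probe set nearest 0 stood at -0.40 for TOP1MT, -0.11 for ZNF704, -0.54 for ENC1 and -0.97 for SGMS2. Of the 58 interferon-stimulated genes, 54 rose, 0 fell and 4 did not pass (57 adjusted over the list alone; median 3.64, adjusted p = 1.62e-155). Over the alternative tests of that list the highest unadjusted p was 7.59e-04.

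MHC class I genes rose as a list (median 0.53, adjusted p = 1.24e-11), with the peptide transporters TAP1 (2.49) and TAP2 (2.03) and the proteasome subunits PSMB9 (1.95) and PSME1 (1.19) passing and 16 of 20 not (6 adjusted over the list alone). So did the checkpoint list (median 0.58, adjusted p = 3.70e-06), where TNFSF10 rose by 5.03 and 17 of 18 did not pass (2 adjusted over the list alone, 4 with the donor block). With the donor block and an estimated correlation their adjusted p were 0.123 and 0.0617. Chemokines rose as a list (median 0.21, adjusted p = 3.22e-04, and adjusted p = 0.177 with an estimated correlation), where CXCL10, CXCL11 (3.31) and CXCL9 (2.46, adjusted p = 0.114 with a larger pseudocount) passed, 4 adjusted over the list alone and 6 with the donor block. Maturation genes rose as a list (median 0.25, adjusted p = 0.00254, and adjusted p = 0.503 with an estimated correlation), with IL15RA (1.96) the 1 of 29 that passed, 1 adjusted over the list alone and 3 with the donor block. CD80 stood at 2.16 (adjusted p = 0.242, and 0.00412 with the donor block), CD83 at -0.01, CCR7 at -0.11, IL6 at 0.15 and FCGR2B at -0.02.

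NF-kB targets were higher as a list, with 18 of 23 above 0 and IRF1 (1.49) the 1 that passed (median 0.21, adjusted p = 0.0170, and adjusted p = 0.628 with an estimated correlation). The cytokine list was called up, with 12 of 22 members above 0 and IL27 (1.89) the 1 that passed (median 0.12, adjusted p = 0.0479, and adjusted p = 0.628 with an estimated correlation), a list call that ended with the donor block (0.0813) and after quantile normalization (0.0817). In the Toll-like receptor list TLR3, a sensor of double-stranded RNA, rose by 1.95, IRF1 by 1.49 and MYD88 by 1.33, and the list was called up (adjusted p = 0.0170, and adjusted p = 0.414 with an estimated correlation). Its mean was 0.22 and its median -0.0013, above 0 under both other scalings. Complement (SERPING1 at 3.84; adjusted p = 0.0300, and adjusted p = 0.606 with an estimated correlation) and metallothionein genes (0 of 16 by limma; adjusted p = 0.0300, and adjusted p = 0.653 with an estimated correlation) were called up as lists, each with an adjusted p of 0.0817 after quantile normalization. Ribosomal protein genes were lower as a list with 0 of 16 passing by limma (median -0.35, adjusted p = 0.00254, and adjusted p = 0.638 with an estimated correlation). The cholesterol (adjusted p = 0.103, STARD4 at 1.29), heat shock (0.371, DDIT3 at 1.88), prostaglandin E2 (0.103), immature cell (0.894), Fc receptor (0.973), MHC class II (0.756), lysosome (0.756), interferon and receptor (0.973) and cell cycle (0.756) lists did not pass. Nor did the monocyte (0.756), T cell (0.973), NK cell (0.973), B cell (0.973), platelet (0.371), erythroid (0.404), neutrophil (0.797) and plasmacytoid dendritic cell (0.440) lists. In the fit with the donor block 2 NF-kB targets were higher, 1 Fc receptor and 1 MHC class II gene lower, and 1 heat shock gene higher and 1 lower. Median, mean and test differed in sign for the lysosome, NK cell, B cell and neutrophil lists. TAP2, PSMB9, PSME1, CXCL11, CXCL9 and MYD88 were chosen after their values were seen.

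A total of 176 genes passed by limma, 147 higher and 29 lower, and 633 passed with the donor as a block (332 higher and 301 lower).

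The genes raised at least 2-fold by interferon alpha, 143 in number and 54 of them in the fixed list, were followed in the other comparisons. With the antibody in dendritic cells 57 of them rose and 1 fell (74 and 3 adjusted over the list alone; median 0.77, adjusted p = 5.30e-29, and 0.00347 with an estimated correlation). With array weights, which widened the set to 335 genes, the median was 0.29. The 89 outside the fixed list had a median of 0.39, with 27 higher and 1 lower. With the cocktail 32 rose and 32 fell (median -0.26, adjusted p = 0.533), and the mean lay below 0 while the test pointed up. In the direct comparison 53 were higher with the antibody and 3 lower (median 0.61, adjusted p = 0.0366 with an estimated correlation, and unadjusted p = 0.0840 with that and the donor block together). In monocytes the median was 0.83 with 0 passing over all genes by limma and 58 adjusted over the list alone (adjusted p = 4.66e-42, and 9.69e-04 with an estimated correlation). The 25 genes lowered by interferon alpha had a median of -0.30 with the antibody in dendritic cells (2 higher and 4 lower; adjusted p = 0.00106, and 0.0175 with an estimated correlation).

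A test of the difference between the antibody and interferon alpha effects in dendritic cells passed for 86 genes, 37 more positive with the antibody and 49 more positive with interferon (596 with the donor block, 299 and 297). CCL5 (difference 4.69, SE 0.95, adjusted p = 0.0144), EBI3 (4.61), IL2RA (4.54), HSD11B1-AS1 (4.28) and SLC1A2 (4.03) had the largest positive differences. NEXN, an actin-binding protein, stood at 0.01 with the antibody and 5.23 with interferon (difference -5.22, SE 0.50, adjusted p = 1.49e-06), and CXCL10 at 0.72 and 5.85 (difference -5.13, SE 0.84). The receptor kinase AXL (-4.29), IFITM2 (-4.12) and HESX1 (-3.84) followed. Interferon-stimulated genes responded less to the antibody (median difference -2.43, 13 of 58 passing, adjusted p = 2.85e-50, and 0.0257 with an estimated correlation), and maturation genes more (1.38, 5 of 29 passing, adjusted p = 5.02e-17, and 0.0122 with an estimated correlation). The count was 49 without no-interferon replicate 1 and 48 without no-interferon replicate 2. Across genes the effects had Pearson r = 0.284 (rho = 0.217), and 57 genes were higher in both where 4.94 would be by independent lists.

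The monocyte comparison asked whether the antibody acts in the same way on the cells from which dendritic cells are grown (n = 3 and 3 for every gene in this comparison). No gene passed by limma over all genes, with 1110 at an unadjusted p under 0.05, 53 passing with the donor as a block (32 higher and 21 lower), 304 with the donor as a random block and 954 with array weights. CXCL10 stood 3.84 higher (SE 0.67, adjusted p = 0.0937, and 0.0201 with the donor block), IFIT1 3.61 higher (SE 0.98, adjusted p = 0.225) and MX1 3.03 higher (SE 0.88, adjusted p = 0.272). IL6 stood at -4.13 (SE 1.40, adjusted p = 0.429, and 0.0403 with the donor block), and CD14 at -1.18, IL10 at -1.26, CCR7 at -0.83, CD86 at 0.97 and FCGR2B at 0.37 did not pass. In simulated data with this design 82.1% of genes changed by 2 on the log2 scale were found. That simulation had no donor effect and no deviating array, so it does not tell what share would be found in these cultures.

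As a list, the 58 interferon-stimulated genes were higher with the antibody (median 1.86, 0 passing over all genes by limma, 46 adjusted over the list alone, 13 with the donor block; adjusted p = 1.08e-56). The adjusted p was 0.0306 with an estimated correlation and 0.168 with that and the donor block together. Their mean level was 8.46, 7.80 and 10.29 on isotype replicates 1 to 3 and 10.76, 10.82 and 10.74 on the antibody arrays. Without isotype replicate 3, 675 genes passed (383 higher and 292 lower), among them 44 of the 58. The count was 1 without antibody replicate 1, 8 without antibody replicate 3, and 293 without both arrays of replicate 3. Cytokine genes were lower as a list (median -0.82, 1 higher and 7 lower adjusted over the list alone, 1 and 2 with the donor block; adjusted p = 2.98e-05, and adjusted p = 0.135 with an estimated correlation). Their mean level was 9.95, 9.07 and 7.58 on isotype replicates 1 to 3 and 7.94, 7.62 and 7.48 on the antibody arrays. Platelet markers moved with them, at 8.25, 8.16 and 6.86 against 7.38, 6.88 and 6.60 (median -0.41, 1 lower adjusted over the list alone; adjusted p = 0.00376, and adjusted p = 0.133 with an estimated correlation).

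No member of any other list passed over all genes by limma in monocytes. Adding the donor block gave 1 chemokine and 1 complement gene as higher, and 1 checkpoint gene as higher and 1 as lower. MHC class II (median 0.81, adjusted p = 0.00173) and lysosome genes (0.36, adjusted p = 0.00340, 4 higher adjusted over the list alone) were higher as lists, each with adjusted p = 0.390 with an estimated correlation. Lower as lists were NF-kB targets (-0.43, adjusted p = 0.00376, and adjusted p = 0.532 with an estimated correlation), metallothionein genes (-0.85, adjusted p = 0.00853, and adjusted p = 0.610 with an estimated correlation) and maturation genes (-0.33, adjusted p = 0.0235, and adjusted p = 0.582 with an estimated correlation). Prostaglandin E2 and cAMP genes (-0.67, adjusted p = 0.0171) and plasmacytoid dendritic cell markers (-0.51, adjusted p = 0.0495) were lower too, each with adjusted p = 0.390 with an estimated correlation. With the donor block the lysosome (0.0757), maturation (0.0537) and prostaglandin E2 (0.0641) calls ended, as did the metallothionein call after quantile normalization (0.0532). The chemokine (adjusted p = 0.313, and 0.0485 with the donor block), T cell (0.171, and 0.0298 with the donor block), MHC class I (0.517, and 4.78e-04 after quantile normalization) and ribosomal protein (0.970, and 4.49e-06 after quantile normalization) lists did not pass. Neither did the immature cell (0.127), Fc receptor (0.303), Toll-like receptor (0.494), complement (0.970), checkpoint (0.124), cholesterol (0.523), heat shock (0.970), cell cycle (0.494), interferon and receptor (0.929), monocyte (0.116), NK cell (0.494), B cell (0.271), erythroid (0.240) and neutrophil (0.442) lists. Median, mean and test differed in sign for the interferon and receptor, complement, heat shock and ribosomal protein lists. The median over all genes was -0.0028, and 0.10 when arrays were scaled to 1 median.

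The antibody effect was tested for a difference between dendritic cells and monocytes, and 257 genes passed, 155 more positive in dendritic cells and 102 more positive in monocytes (2120 with the donor block, 877 and 1243). IL6 stood at 3.75 in dendritic cells and -4.13 in monocytes (difference 7.87, SE 1.78, adjusted p = 0.0228), and IDO1 at 5.16 and -1.78 (difference 6.94, SE 1.17, adjusted p = 0.00243). MUCL1 (8.78, SE 1.65), MMP1 (7.96, SE 2.00) and DUSP4 (6.70, SE 1.04) had differences of the same sign. CD36, a scavenger receptor, stood at -2.17 and 3.08 (difference -5.26, SE 1.02, adjusted p = 0.00728), and the retinol dehydrogenase DHRS9 (-4.73), LPAR6 (-4.25), IL1R2 (-3.85) and RCBTB2 (-3.83) went the same way. Cytokine genes differed by a median of 2.00 (6 of 22 passing, adjusted p = 5.22e-11, and 0.00869 with an estimated correlation), maturation genes by 1.99 (11 of 29, 1.11e-23, and 0.00194) and NF-kB targets by 1.98 (12 of 23, 8.25e-22, and 0.00688). For interferon-stimulated genes the median difference was -0.62 with 1 of 58 passing, ISG20 (3.40; adjusted p of the list = 0.0438, and adjusted p = 0.713 with an estimated correlation).

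The count of 257 was 150 without dendritic cell antibody replicate 2 and 392 without replicate 3. It was 71, 138 and 1344 without monocyte isotype replicate 1, 2 or 3, and 117 without monocyte antibody replicate 2. Across genes the antibody effects in the 2 cell types had Pearson r = -0.222 (rho = -0.217), which was -0.0678 without monocyte isotype replicate 1. The median of all differences was -0.0452, and -0.138 when arrays were scaled to 1 median.

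**Figure D4:**
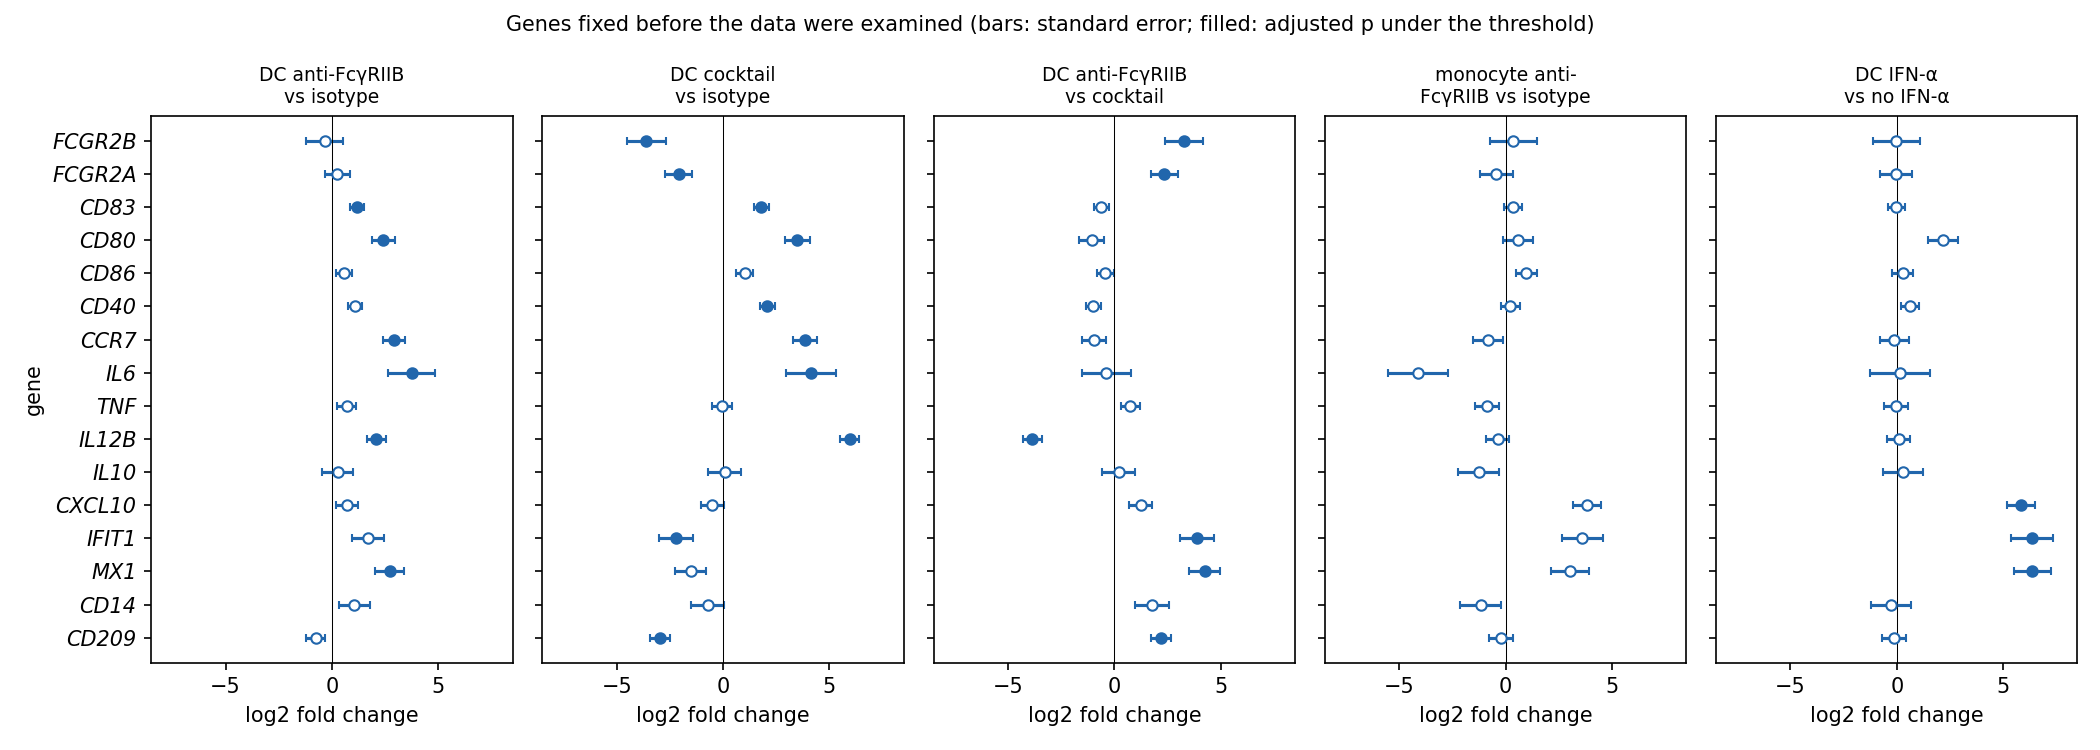
Log2 fold change (points, filled where the adjusted p passed) and SE (bars) of the genes fixed in advance in each of the 5 comparisons. IL6 stood at 3.75 with the antibody in dendritic cells and at -4.13 in monocytes.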

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

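Among the tests in this part, those of an already high interferon-stimulated level, of degraded RNA and of an unstimulated culture in dendritic cell replicate 3, of the shared isotype arrays, and of separate donors were chosen only after the result was seen.

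The first pattern is in monocytes, where the interferon-stimulated genes of replicate 3 differed little between antibody and isotype, although 54 of 58 were still higher with the antibody, by a median of 0.36. If the isotype array of replicate 3 had held RNA of an antibody-treated culture, its difference should not follow the other pairs, and the correlation across genes with the mean of the other 2 pairs was 0.0476, which leaves that open. That array may instead have held a high interferon-stimulated level of its own. Its list level lay 1.83 above the nearest other isotype array while the antibody arrays ranged over 0.089, which restates the pattern and does not decide between the 2. The pair also differed little outside the list. Its differences had an SD across genes of 0.408, against 0.871 and 0.750 in replicates 1 and 2. With the list left out, their correlation with the mean of the other pairs was 0.0304, against 0.403 and 0.430. A high level of the list alone would not account for those other genes. For the listed genes both explanations remain open, and no biological explanation was tested.

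The second pattern is in dendritic cells, where the interferon-stimulated genes of replicate 3 also differed little. Degraded RNA on the isotype array is argued against as the whole cause, because the antibody array set against the other 4 isotype arrays still differed by only 0.0893, where the other antibody arrays differed by 1.05 to 2.02. In a culture that never received the antibody the maturation genes of that pair should differ little. Their median difference was 1.49, with 1.70 as the lowest of the other pairs. Across genes the difference of that pair correlated at 0.464 with the mean of the other pairs (0.471 without the interferon-stimulated list). The other replicates had 0.618 to 0.714. Both results argue against such a culture only as far as isotype replicate 3, with its high 3' to 5' control ratios, serves as a baseline. The maturation genes were not set against the other 4 isotype arrays, so this explanation stays open. A response of this donor's cells that differs in its interferon part could account for the pattern and stays open as untested.

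The third pattern is the likeness of antibody and cocktail effects in dendritic cells. The shared isotype arrays alone are argued against as the whole cause, because over 20 splits that gave each contrast its own isotype arrays the lowest correlation across genes was 0.555. Donors shared by the 2 contrasts are argued against as the whole cause too, because with the antibody effect taken in some donors and the cocktail effect in the others it was 0.511 at the lowest over 10 splits. The RNA quality of isotype replicate 3 is argued against in the same way, with a lowest correlation of 0.537 over 12 splits of the other 4 isotype arrays and of 0.504 over 3 splits of the other donors. A common maturation response could account for the rest and stays open as untested.

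Single arrays that stood apart from the rest of their group were sought by the gap to the nearest array over the range of the group. A high ratio can come from a small gap where the other arrays lie close together. Groups of 3 arrays were too small for this rule, so no monocyte or interferon array was examined. Chance flags about 1 in 20 groups, and 16 of 217 tests of genes, 2 of 87 of list levels and 2 of 6 of control ratios met the limit, where 10.85, 4.35 and 0.3 would by chance. On dendritic cell isotype replicate 3 the ratio was 0.963 for the 3' to 5' control ratio of GAPDH, 0.965 for that of ACTB, 0.858 for CD40 (lower) and 0.783 for SLC1A2 (higher). On antibody replicate 3 it was 0.774 for the level of the interferon alpha response genes (8.38 against 9.18 to 9.41), 0.718 for IFITM3 (lower) and 0.756 for CD1A (higher). Cocktail replicate 2 had 0.891 for the lysosome list (9.78 against 10.64 to 10.75). It had 0.939 for CD86 (13.561 against 13.668 to 13.675) and 0.865 for IFI27 (5.03 against 4.89 to 4.91), both small gaps. Cocktail replicate 5 was higher in C1QC (0.890), HK3 (0.920) and LY6E (0.936). Cocktail replicate 4 gave 0.878 for IDO1 (14.175 against 14.101 to 14.11, a small gap) and 0.877 for IL6 (9.66 against 11.97 to 12.30). Cocktail replicate 3 gave 0.915 for TNF (7.51 against 7.06 to 7.10). CXCR2 in isotype replicate 2 (0.794), SLAMF8 in isotype replicate 5 (0.741), IL12B in antibody replicate 2 (0.759) and XCL1 in antibody replicate 5 (0.727) also met the limit.

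The antibody effect differed between dendritic cells and monocytes for 257 genes by a test of the difference itself. The largest differences were 8.78 for MUCL1, 7.96 for MMP1, 7.87 for IL6, 6.94 for IDO1 and 6.70 for DUSP4, and -5.26 for CD36, -4.73 for DHRS9, -4.25 for LPAR6, -3.85 for IL1R2 and -3.83 for RCBTB2.

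A signal also appeared in probe sets that no comparison of the report uses, the 7280 that passed the filter and name no gene (5938) or several (1342). By limma 81 of them passed with the antibody in dendritic cells, 592 with the cocktail, 119 in the direct comparison and 18 with interferon alpha. In monocytes 0 passed, with 357 at an unadjusted p under 0.05.

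Other splits of the arrays were used to ask whether chance could be excluded. Over all splits drawn, the share as large lay under 0.05 for the 938 genes of the antibody comparison in dendritic cells (1 of 100, the real one, highest other 134). It did for the 3902 of the cocktail comparison (1 of 100, highest other 2325, the real split with isotype replicate 1 moved to the cocktail arrays). For the response genes of interferon alpha with the antibody it did by a narrow margin (1 of 100, median 0.767, highest other 0.749). The split with 0.749 was the real one with antibody replicate 3 and isotype replicate 1 exchanged. The share lay under 0.05 for the 1091 of the direct comparison too (2 of 100), where 1 other split reached 1127. That split placed antibody replicate 2 with the 4 cocktail arrays. Splits so close to the real one keep most of its grouping, so their high values are partly built in. Most of the splits drawn left donor pairs together, so they are no like reference for paired arrays. Only 13 of the splits in each case, the real one included, part as many donor pairs, which is too few for a share under 0.05. Among those the highest others were 2 for the antibody, 0.726 for the response genes, 2325 for the cocktail and 19 for the direct comparison. Chance was therefore not excluded for these results. Nor was it for the difference between cell types (8 of 100 as large, 257 and a highest other of 1189) or between antibody and interferon (6 of 100, 86 and 107). The highest others there left donor pairs together, and among the 7 and 4 splits parting as many pairs they were 0 and 26. The splits were too few for interferon alpha (1 of 10 as large; 176, highest other 16), for the response genes in monocytes (1 of 10; 0.832, highest other 0.720) and for the genes in monocytes (10 of 10; 0, highest other 1469). That last split, isotype replicates 1 and 2 with antibody replicate 1 against the rest, points to a structure of the samples, and splits parting all 3 pairs gave 0 at most. The 1189 for the difference between cell types came from the same regrouping of the monocyte arrays. That split regrouped the dendritic cell arrays as well, so its count cannot be put down to the monocytes alone.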

How the results depend on the processing

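Leaving out whole donors, leaving out 2 isotype arrays together, and the donor block with an estimated correlation were tests added after the data were seen. Named genes were followed under quantile normalization, the donor block and the larger pseudocount only, and none reversed there. None of the lists followed here reversed. The genes that passed with the antibody turned from 519 higher and 419 lower to 1149 and 1582 with the donor block. Those that differed between cell types turned from 155 and 102 to 877 and 1243. Counts of genes that pass depended most on how the donor and the array spread were modelled, and on single arrays in monocytes, while the signal over background limits genes near the level of the filter. The lists followed were the interferon-stimulated genes in the 5 comparisons, maturation in the 3 comparisons among antibody, cocktail and isotype, cytokines with the antibody in both cell types, and NF-kB targets with the antibody in dendritic cells. They kept their direction and their side of an unadjusted p of 0.05, with the exception named below. On adjusted p the cytokine list in monocytes and the interferon-stimulated and maturation lists in the direct comparison lost their call with an estimated correlation, and the interferon-stimulated list in dendritic cells with the antibody and in monocytes, and the cytokine list in dendritic cells, with that and the donor block together. Of 296 results for named genes, 288 kept their call and 8 lost it after quantile normalization, 8 gained one with the donor block, and 4 lost and 1 gained one with the larger pseudocount.

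In the order antibody, direct comparison, monocyte, interferon alpha, difference between cell types, and difference between antibody and interferon, the counts were 2731, 2692, 53, 633, 2120 and 596 with the donor as a fixed block, 2711, 2737, 304, 672, 2156 and 683 as a random block, and 1468, 1733, 954, 958, 1710 and 526 with array weights. Scaling to 1 median gave 620 for the antibody and 1 for monocytes. The larger pseudocount gave 136 for the difference between antibody and interferon. In monocytes the mean of a gene's probe sets gave 4 and all probe sets gave 1. Fitting only the arrays compared, with fewer arrays to estimate the spread, gave 113 for interferon alpha and 86 for the difference between cell types. Requiring 2-fold, which removes genes by construction, gave 2540 for the cocktail, and the donor block with the 2 coded interferon pairs only gave 284. Leaving out dendritic cell isotype replicate 3 and monocyte isotype replicate 1 gave 55 for the difference between cell types. The interferon-stimulated list in the direct comparison lost its call with the donor block and an estimated correlation (unadjusted p = 0.0643, range over its alternatives 4.80e-32 to 0.0643). For the others the cause was not tested.

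Leaving out each array or each donor in turn gave 324 to 1086 genes for the antibody, 2897 to 3728 for the cocktail, 518 to 1380 for the direct comparison, 0 to 675 for monocytes, 82 to 152 for interferon alpha, 36 to 1344 for the difference between cell types and 21 to 125 for that between antibody and interferon. The lowest came from leaving out all arrays of 1 donor except in monocytes (isotype replicate 1 among others), and the highest for monocytes and cell types came without monocyte isotype replicate 3. The median of the interferon alpha response genes was 0.715 to 1.11 in dendritic cells and 0.651 to 1.26 in monocytes, and 0.292 (array weights) to 1.08 and 0.451 to 1.24 over the other alternatives. Unadjusted p for the interferon-stimulated list were 2.70e-44 to 1.71e-25 (antibody), 0.121 to 0.263 (cocktail), 2.25e-47 to 2.40e-24 (direct), 1.10e-64 to 1.72e-35 (monocytes) and 4.47e-158 to 1.69e-123 (interferon). For maturation they were 2.31e-37 to 2.51e-32 (antibody), 3.06e-29 to 2.23e-26 (cocktail) and 1.37e-11 to 2.93e-08 (direct). Cytokines had 1.59e-10 to 3.37e-07 (antibody) and 8.82e-09 to 9.48e-04 (monocytes), and NF-kB targets 6.96e-30 to 8.17e-26 (antibody).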

Other observations

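Further members of the interferon-stimulated list passed with the antibody in dendritic cells, chosen here after their values were seen. ISG20 was higher by 3.73 on the log2 scale, IFI27 by 3.61, GBP1 by 2.82, ISG15 by 2.61, RSAD2 by 2.21 and IRF7, which drives interferon alpha transcription, by 2.03.

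Across genes the antibody effect in monocytes and the interferon alpha effect in dendritic cells had Pearson r = 0.138 and Spearman rho = -0.0248. That r was 0.256 without monocyte isotype replicate 1 and 0.0753 without monocyte isotype replicate 3. Cocktail and interferon alpha effects in dendritic cells had r = 0.0939 and rho = 0.135. Genes are not independent replicates, and no p was computed across them. In monocytes, the interferon alpha response genes outside the fixed list had a median of 0.45, with 0 passing over all genes by limma and an adjusted p of 9.98e-04 with an estimated correlation.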
